A study of Mus musculus with 18 samples.

How the data were processed

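Lungs of male C57BL/6J mice were profiled by droplet single-cell RNA sequencing in 6 groups: control, bleomycin and bleomycin with nintedanib, each at day 7 and at day 14. Each group held 3 libraries, and each library was a pool of cells from 3 mice, so replicates are separate pools and 54 mice were used in all. Nintedanib was given at 50 mg/kg from day 0 to 6 in the day 7 mice and from day 7 to 13 in the day 14 mice. Lungs were dissociated mechanically and enzymatically, and mononuclear cells were taken from lymphocyte separation medium, a density-gradient separation of immune cells. Shares of cell classes are therefore shares of the cells that passed this gradient, not of the whole lung. Libraries were made with the Chromium 3' kit, version 2. Cell Ranger and Seurat are named in the submitters' processing notes, but the filters and settings used with Seurat are not given in the sources used here.

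The deposited files hold raw counts of unique molecular identifiers (UMIs) as the authors' pipeline wrote them, for 48795 genes and 737280 barcodes per library, before any selection of cells. Values are whole numbers, so count models were used. Total UMIs per library ranged from 5795451 to 22902091 (median 11592643.5). Barcodes were kept as cells with at least 300 detected genes, at least 500 UMIs and at most 10% mitochondrial UMIs. Of 70217 barcodes past the size limits, 202 were removed for mitochondrial RNA, and 2300 of the remaining 70015 were left out as doublets after clustering. Doublets were the cells with the highest scrublet scores in each library, at 0.8% per 1000 cells. The automatic threshold of scrublet would have marked 670. The 67715 cells kept came to 2748 to 5818 per library, with median UMIs per cell of 1206.5 to 2924 and median genes of 680 to 1235.5. Cells held 79.3% to 92.0% of the UMIs of their library. Barcodes with fewer than 50 UMIs gave the profile of free RNA of each library.

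Counts were normalised per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and a graph of 20 neighbours was clustered by the Leiden algorithm at resolution 1.0 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). The 39 clusters were named with 21 marker lists fixed before the data were examined. Of these, 29 received a name and were joined into 17 classes, and 10 were left unnamed. Unnamed clusters held 4.51% to 7.78% of cells in the 6 groups, and their cells stay in the denominator of every share. Classes are called by the cell they resemble. The alveolar macrophage-like class and the class of interstitial or monocyte-derived macrophage-like cells, called interstitial macrophage-like below, carry the main comparisons. A cluster of proliferating macrophage-like cells (1148 cells before doublets were left out, 76.9% of them from libraries with replicate number 1) was kept out of both.

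Counts were summed per class and library where the class had at least 20 cells in that library, as it had in all 18 libraries for both macrophage classes. Alveolar macrophage-like sums came from 115 to 1007 cells, and interstitial macrophage-like sums from 20 to 37 cells in controls and 325 to 1133 in the other groups. Genes passing filterByExpr (8479 and 10140 in the 2 classes) were tested with edgeR 4.0.16 (TMM scaling, quasi-likelihood fit over all 6 groups, R 4.3.3). The contrasts were bleomycin minus control and bleomycin with nintedanib minus bleomycin, at each day, the mean of the 2 nintedanib contrasts, and the difference of each effect between days. All tests were two-sided and adjusted by Benjamini and Hochberg over the genes of a contrast, with a threshold of 0.05. Changes are log2 fold changes with standard errors, computed as the size of the change over the square root of F, and levels are mean counts scaled to library size (CPM) with the SD over 3 libraries. With 3 libraries against 3 the smallest exact two-sided p is 0.1, so calls rest on variance shared across genes. Where the control counts of a gene sum to 0, the change is given as a lower bound from a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with its counting interval.

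The 18 gene lists were also fixed at that stage: fibrosis-associated macrophage, alternative activation, proinflammatory, interferon response, MHC class II presentation, proliferation, cholesterol synthesis, lipid handling, growth factors, nintedanib target kinases, complement, uptake of dead cells and lysosome, glycolysis and hypoxia, p53 response, chemokines, dissociation and immediate early genes, resident alveolar macrophage identity and interstitial macrophage identity. Each was tested with camera (limma 3.58.1) at the preset correlation of 0.01 and again with an estimated correlation, adjusted over the 18 lists of a contrast. A list is said to pass at the preset correlation. The number of its genes passing is given over all genes and adjusted over the list alone. Genes higher and lower in bleomycin at the other day (at most 200 each) were tested in the same way under nintedanib, so that set and test share no library. Genes are named by a rule written beforehand: adjusted p under 0.05, at least 20 CPM, no overlap between the 2 groups, at most 10 with the largest change in each direction, and the 4 members of a list with the smallest p. Genes named outside it are marked as chosen after their values were seen. Counts of genes include 5 genes that are not reported here by name.

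Class shares were compared as the mean over the days of the difference in mean log2 share, with 0.5 cells added, by exact permutation of groups within day. The 400 arrangements allow no p below 0.005. Values were adjusted over classes and both contrasts. Clusters of macrophage-like cells were compared in the same way as shares of those cells. Median changes of the lists under nintedanib were also averaged within clusters, weighted by cells, which was chosen after the lists had been seen.

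Libraries carry replicate numbers that may mark pools handled together, which the labels do not state. A correlation of residuals within replicate number of 0.1 or more, in all 3 pairs of a contrast, was taken as pairing. It was met by alveolar macrophage-like cells for bleomycin day 14 (0.112 to 0.201) and nintedanib day 14 (0.247 to 0.370), and by interstitial macrophage-like cells for nintedanib at day 7 (0.223 to 0.256) and day 14 (0.228 to 0.328). The cutoff was fixed beforehand, but its use per class and contrast was chosen after counts with a replicate block had been seen. Values with the block are given beside the main ones in those contrasts where they change a call or move a count by more than 1.5 times.

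Alternatives were DESeq2 1.42.0, relative log expression (RLE) scaling, no expression filter, the replicate block, only the groups of a contrast in the fit, stricter cell filters, doublets kept, classes from marker scores per cell, free RNA subtracted, libraries thinned to the smallest, each library left out, smaller sets, an estimated correlation, edgeR on cell counts, another denominator, a finer clustering, and clustering without the genes called. Of 25 pairs of a result and an alternative, 2 were chosen after seeing the data. The design was also tested on simulated data with 200 genes changed in each round. For a log2 change of 1, edgeR recovered 55.7% and 63.6% of genes for bleomycin at days 7 and 14 in alveolar macrophage-like cells, and 12.0% and 12.2% in interstitial macrophage-like cells, whose control sums are small. For nintedanib it recovered 49.5% and 79.8%, and 79.4% and 77.6%. False calls made up 8.70% of the calls for bleomycin and 13.6% for nintedanib at day 14 in interstitial macrophage-like cells, above the 5% aimed at, and under 5% in the other 6 contrasts. A doubled share was found at p under 0.05 in 100% of rounds, but in 10% after adjustment. That simulation held 12 classes and no bleomycin effect. In the data, bleomycin classes with the smallest possible p ease the shared adjustment, so the 10% does not give the power there. Every arrangement of 3 libraries against 3 was also fitted for each contrast, and 30 drawn arrangements for contrasts over both days.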

Results

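Bleomycin increased the shares of interstitial macrophage-like cells and conventional and migratory dendritic cell-like cells among lung cells recovered by density-gradient separation of immune cells (lymphocyte separation medium). It decreased the shares of nonclassical monocyte-like, basophil or mast cell-like and B cell-like cells. A higher share of some classes lowers the shares of the others, and absolute cell numbers were not measured. Interstitial macrophage-like cells, which here include macrophages that arise from monocytes, rose from 0.745 ± 0.245% of cells to 15.1 ± 2.24% at day 7 and from 0.989 ± 0.179% to 21.3 ± 2.42% at day 14 (mean ± SD of 3 pools), 20.9-fold over both days (log2 4.38). Conventional dendritic cell-like cells rose from 1.29 ± 0.506% to 4.37 ± 1.74% and from 1.42 ± 0.200% to 3.002 ± 0.828% (log2 1.40). Migratory dendritic cell-like cells, the Ccr7 expressing form that carries antigen to lymph nodes, rose 7.16-fold (log2 2.84). Nonclassical monocyte-like cells, which patrol the vessel wall, fell from 4.10% to 1.99% and from 4.30% to 1.76% (log2 -1.18), and basophil or mast cell-like cells fell from 1.16% to 0.679% and from 1.18% to 0.543% (log2 -0.98). In these 5 classes the bleomycin and control pools did not overlap on either day (exact permutation p = 0.005, the smallest possible, adjusted p = 0.0283). B cell-like cells fell from 18.7% to 11.3% and from 16.7% to 11.3% (log2 -0.65, exact p = 0.01, adjusted p = 0.0486), without overlap at day 7 only. With 1 of the 3 day 7 control pools left out, 3 classes passed. The other 11 classes did not pass. Among them, alveolar macrophage-like cells were 11.6 ± 3.27% in controls and 5.03 ± 1.57% in bleomycin at day 7, and 13.1 ± 5.61% and 16.2 ± 6.78% at day 14. The exact p of 0.27 is for the mean of 2 effects that go opposite ways (log2 -1.21 and 0.31). At day 7 the pools did not overlap (exact p = 0.1, the smallest possible on 1 day), and the difference between days had exact p = 0.06 (adjusted p = 0.578).

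Nintedanib given with bleomycin lowered the share of basophil or mast cell-like cells further, from 0.679 ± 0.249% to 0.288 ± 0.126% at day 7 and from 0.543 ± 0.204% to 0.178 ± 0.0313% at day 14. The log2 change was -1.35 with no overlap of pools on either day (exact permutation p = 0.005, adjusted p = 0.0283). These cells carry the high-affinity IgE receptor and were defined by Cpa3, Mcpt8 and Ms4a2, among other markers. It was the 1 class of 17 that passed. The adjustment was shared with the bleomycin contrast, where other classes also had the smallest possible p. Adjusted over the 17 nintedanib values alone, an exact p of 0.005 in 1 class would not pass. With exact permutation, 0 classes passed without day 7 bleomycin pool 1 or 2 or without day 14 nintedanib pool 2 (2 of 17 had an unadjusted p under 0.05 with all pools), and 2 passed without day 7 nintedanib pool 1. Interstitial macrophage-like cells made up 15.1% of cells with bleomycin and 16.0 ± 3.96% with nintedanib at day 7, and 21.3% and 25.2 ± 3.80% at day 14 (log2 0.15, exact p = 0.315, adjusted p = 0.502). Alveolar macrophage-like cells made up 5.03% and 4.38%, and 16.2% and 19.5 ± 5.89% (log2 0.06, exact p = 0.795, adjusted p = 0.81). Of 7 clusters of macrophage-like cells, 5 differed in share between bleomycin and control (4 higher, 1 lower) and 1 between nintedanib and bleomycin. This was cluster 25, marked by Rsad2 and Cxcl10, which was lower with nintedanib (5.33 ± 1.41% to 2.93 ± 1.68% at day 7, 2.29 ± 0.654% to 1.37 ± 0.359% at day 14; log2 -0.87, exact p = 0.015, adjusted p = 0.035). This call also rests on the adjustment shared with bleomycin, and over the 7 nintedanib values alone an exact p of 0.015 would not pass. Cluster 25 did not pass with marker-score classes, edgeR on cell counts or a finer clustering. Nor did a cluster pass by exact permutation (1 of 7 with unadjusted p under 0.05 with all pools) without pool 1 or 3 of either day 14 group, pool 2 of either day 7 group or day 7 bleomycin pool 3. When the macrophage-like cells were clustered again without the genes called between groups, an alternative chosen after the data were seen, 9 of 16 clusters differed in share between bleomycin and control (7 higher, 2 lower), and 0 of 19 between nintedanib and bleomycin, where exact permutation gave an unadjusted p under 0.05 in 0 clusters.

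**Figure D1:**
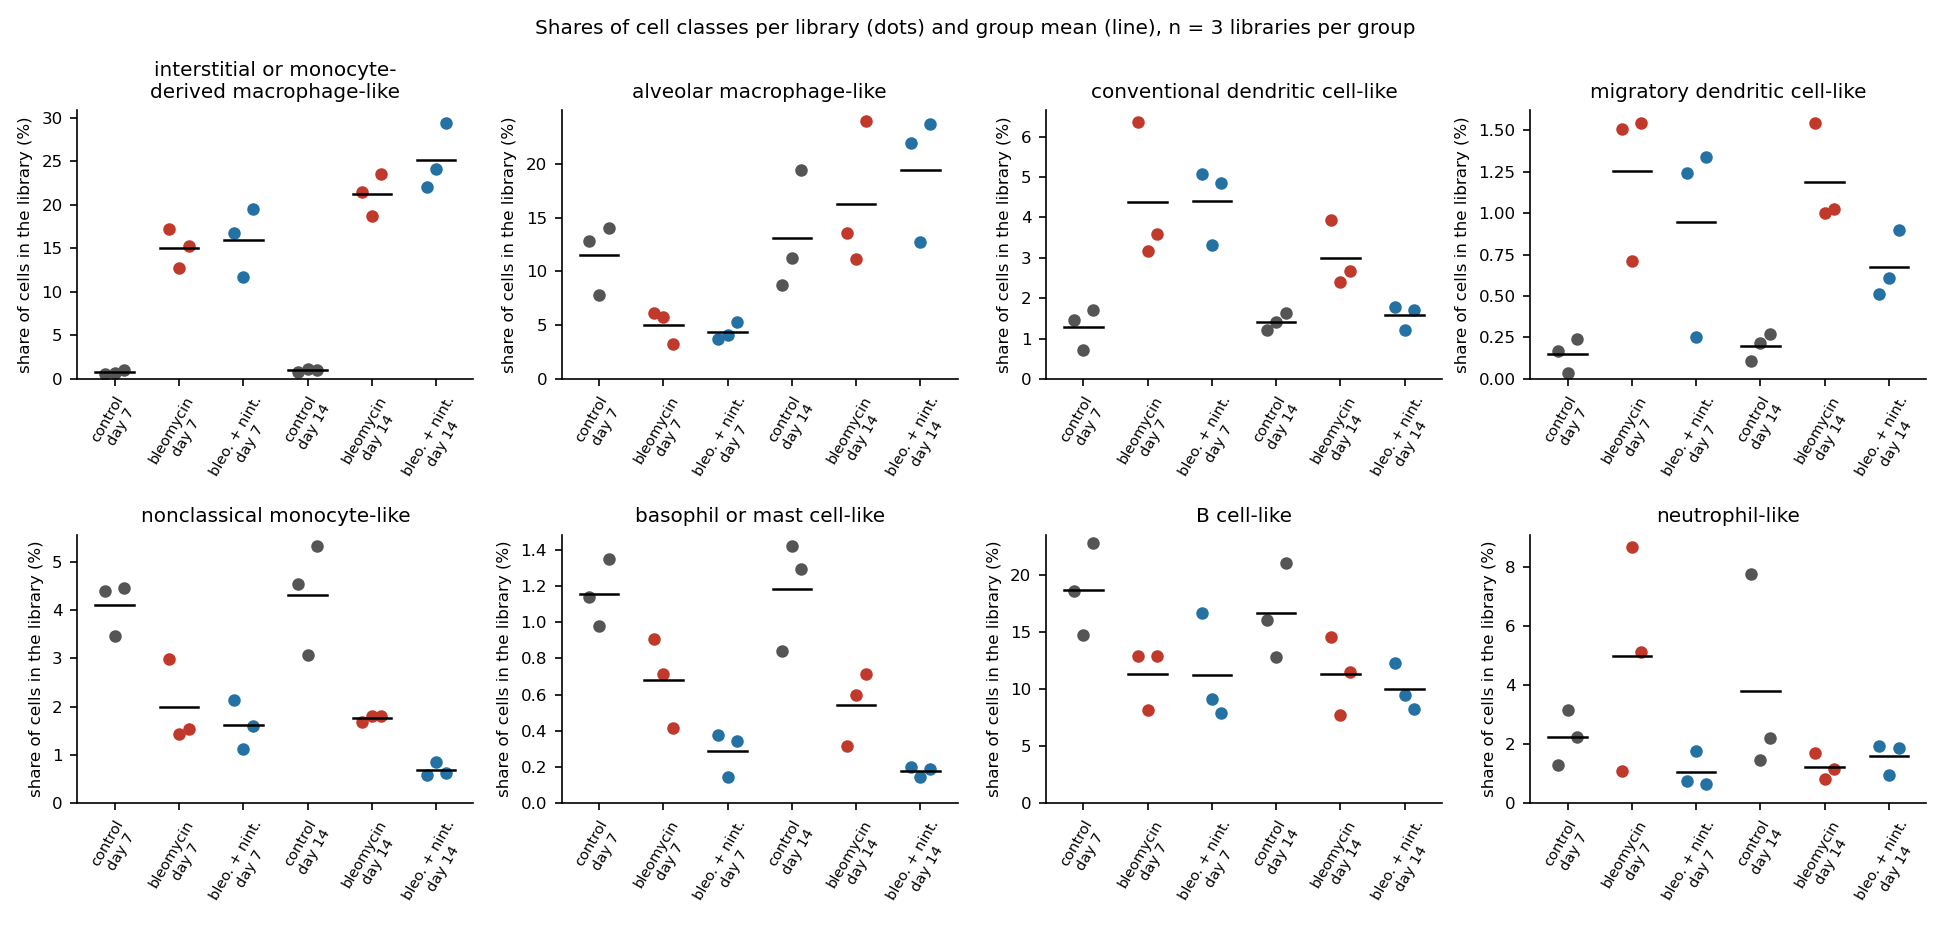
Shares of cell classes among all retained cells, by group and day. Each point is 1 pool of 3 mice.

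In alveolar macrophage-like cells, the airspace macrophages that clear surfactant, bleomycin raised Arg1, the C1q genes and Msr1 and lowered Cidec, Fabp1 and Krt79 at day 7. Arg1, the arginase that supplies ornithine for polyamine and proline synthesis, was nearly absent in controls (0.232 CPM). It reached 97.5 ± 25.1 CPM at day 7, a ratio of 337 (60.03 to 13369.6). The complement gene C1qb rose by 7.42 ± 0.52 on the log2 scale (standard error; 2.85 to 323 CPM), with C1qc (6.60 ± 0.66) and C1qa (6.25 ± 0.64). The scavenger receptor gene Msr1 rose by 5.75 ± 0.29 (adjusted p = 8.08e-13). Syngr1, which encodes a vesicle membrane protein, rose by 5.66 ± 0.59. The secretory kinase gene Fam20c rose by 4.87 ± 0.47 and AA467197, a small transcript induced in inflammation, by 4.62 ± 0.29. Cidec, which builds large lipid droplets, fell from 278 to 43.3 CPM (-2.73 ± 0.26, adjusted p = 5.24e-08). The fatty acid-binding protein gene Fabp1 (-2.61 ± 0.43), the keratin gene Krt79 (-2.58 ± 0.37), the polarity gene Inadl (-2.65 ± 0.32) fell with it. The peroxisomal thiolase gene Acaa1b (-2.52 ± 0.26), the copine gene Cpne5 (-2.52 ± 0.31) and the sphingomyelin synthase gene Sgms2 (-2.27 ± 0.31) were lower too. The haemoglobin RNAs Hba-a1 (-2.96 ± 0.92), Hba-a2 (-2.69 ± 0.91) and Hbb-bs (-2.67 ± 0.78), which come from erythroid cells, also fell. In total 1370 of 8479 genes passed at day 7 (756 higher, 614 lower), and 801 without day 7 control pool 1.

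At day 14, 2049 genes passed (1047 higher, 1002 lower). Arg1 rose from 0.489 to 117 ± 17.8 CPM (ratio 364, 65.2 to 14401), C1qb by 7.36 ± 0.43 (5.40 to 806 CPM, adjusted p = 5.45e-12), C1qa by 7.01 ± 0.56 and C1qc by 5.77 ± 0.50. The largest increases also included the lactate dehydrogenase gene Ldhb (ratio 160, 44.1 to 1321.9), the membrane collagenase gene Mmp14 (ratio 76.3, 20.96 to 632.4), Ccl17, a chemokine for CCR4-bearing T cells (5.74 ± 0.69), and Marcks, a regulator of actin at the membrane (5.15 ± 0.51). Msr1 (5.40 ± 0.25) and Syngr1 (5.43 ± 0.47) rose again. Krt79 fell from 571 to 12.2 CPM (-5.31 ± 0.43) and Fabp1 from 787 to 24.5 CPM (-5.07 ± 0.48). Ear1, an eosinophil-type ribonuclease typical of resident cells, fell from 1116 to 91.3 CPM (-3.62 ± 0.25). Inadl (-4.24 ± 0.31), Cpne5 (-4.20 ± 0.32), Cidec (-4.04 ± 0.27), Acaa1b (-3.99 ± 0.25), the keratin gene Krt19 (-3.92 ± 0.51), the nuclear envelope gene Syne2 (-3.72 ± 0.32) and the lipolysis inhibitor gene G0s2 (-3.49 ± 0.36) fell too. In every gene named so far, the 3 bleomycin pools lay on 1 side of the 3 controls, which the naming rule requires. The same held for 31.5% of tested genes at day 7, against 10% by chance for unpaired libraries, and for 38.2% at day 14. The day 14 share has no chance value here, since that contrast met the criterion for pairing by replicate number. The days shared 588 higher genes (93.4 for independent lists) and 455 lower genes (72.6). Cluster 8, marked by Marco and Ear1, held 97.9% of the class in day 7 controls and 97.6% in day 14 controls. Cluster 5, marked by Chil3 and Olr1, held 40.9% and 87.0% of it after bleomycin, so the values compare different states of the class.

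**Figure D2:**
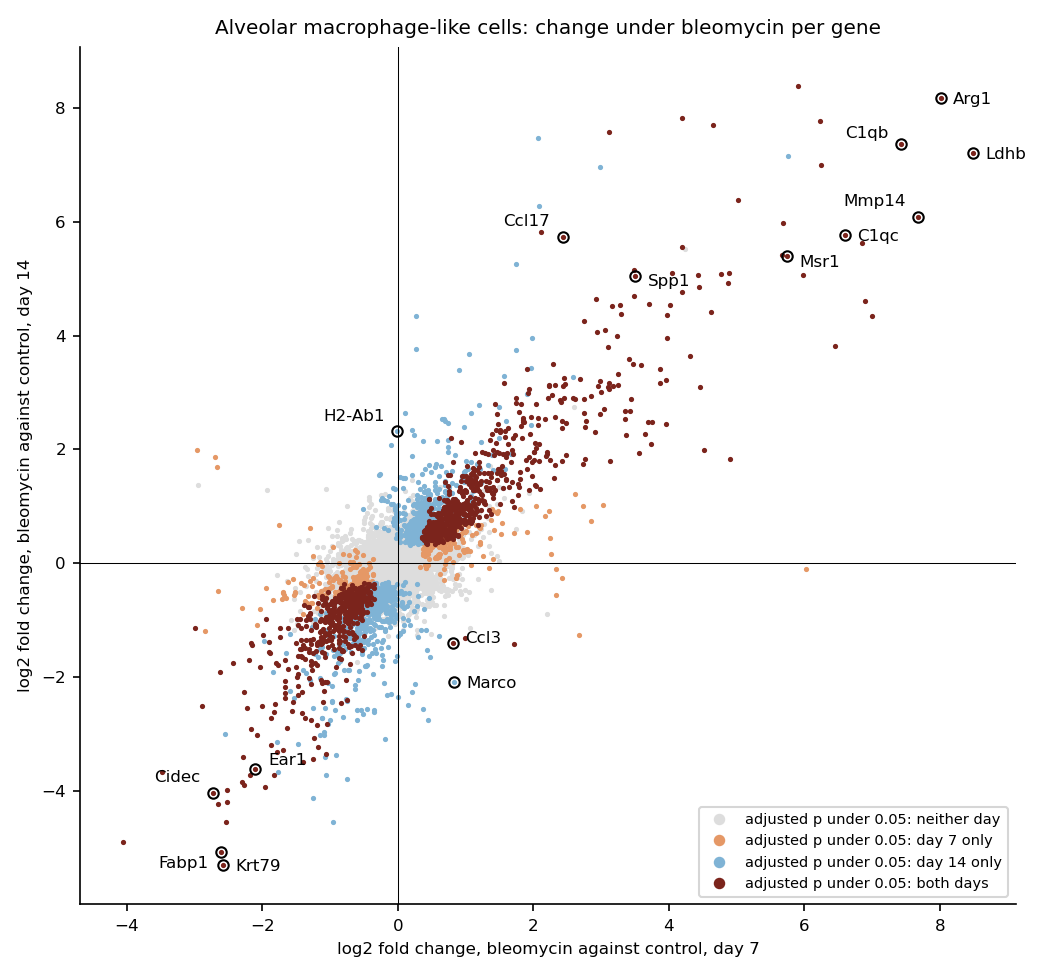
Changes between bleomycin and control in alveolar macrophage-like cells at day 7 and day 14, gene by gene.

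Fibrosis-associated macrophage genes rose in alveolar macrophage-like cells on both days, 10 of 13 at day 7 (11 adjusted over the list alone; median 1.49, adjusted p = 1.24e-12) and 11 at day 14 (11 adjusted over the list alone; median 1.94, adjusted p = 4.62e-11). They included Spp1, the osteopontin gene (466 to 5253 CPM, 3.51 ± 0.27; then 525 to 17405 CPM, 5.06 ± 0.29), the lipid receptor gene Trem2 (2.44 ± 0.18 and 3.12 ± 0.18) and the matrix gene Fn1 (2.22 ± 0.20 and 2.90 ± 0.20). Cholesterol synthesis rose as a block, 12 of 16 genes at day 7 (15 adjusted over the list alone, adjusted p = 1.25e-11) and all 16 at day 14 (16 adjusted over the list alone, adjusted p = 8.82e-11). Among them was Sqle, which opens the sterol branch (2.31 ± 0.33 and 2.57 ± 0.31). Glycolysis and hypoxia genes rose, 6 and 7 of 12 (8 on each day adjusted over the list alone; adjusted p = 2.48e-06 and 2.98e-05). They included Ldha (0.91 ± 0.12 and 0.89 ± 0.12) and the glucose transporter gene Slc2a1 (1.51 ± 0.38 and 2.34 ± 0.34). Genes for uptake of dead cells and lysosome rose, 5 and 6 of 10 with 1 lower at day 14 (5, and 7 with 1 lower, adjusted over the list alone; adjusted p = 3.35e-05 and 7.98e-06). Among them were the bridging protein gene Mfge8 (2.04 ± 0.36 and 2.79 ± 0.35) and the protease gene Ctsb (1.01 ± 0.13 and 1.27 ± 0.13). Interstitial macrophage identity genes rose, 8 and 7 of 10 with 1 lower at day 14 (8 with 1 lower on each day adjusted over the list alone; adjusted p = 1.21e-05 and 7.15e-06), with the lipoprotein gene Apoe (3.24 ± 0.38 and 3.99 ± 0.39). Complement rose with 7 of 9 genes on both days while 1 fell (7 adjusted over the list alone on both days, with 1 and 2 lower; adjusted p = 9.25e-05 and 0.000205). Growth factors rose with 4 of 7 (4 adjusted over the list alone on both days; adjusted p = 0.00111 and 0.0111), Igf1 by 1.44 ± 0.31 and 2.11 ± 0.28.

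Other groups passed with less certainty or on 1 day. Resident alveolar macrophage identity fell, 6 and 8 of 13 genes (6, and 10 with 1 higher, adjusted over the list alone; adjusted p = 0.000534 and 6.26e-08). With an estimated correlation its adjusted p was 0.245 and 0.0693. Interferon response rose, 7 and 5 of 9 (7 and 5 adjusted over the list alone; adjusted p = 6.39e-07 and 0.000532; at day 14 adjusted p = 0.142 with an estimated correlation), with Ifi27l2a, a small mitochondrial protein gene, at 3.59 ± 0.30 and 3.48 ± 0.29. Proinflammatory genes rose at day 7, 8 of 15 (9 adjusted over the list alone; adjusted p = 8.66e-05). Their adjusted p was 0.0564 with an estimated correlation. The neutrophil attractant gene Cxcl1 rose by 3.02 ± 0.46 and the cytokine gene Il1b by 1.93 ± 0.18. At day 14 Il1b stayed high (1.87 ± 0.17) while Tnf (-2.32 ± 0.31) and Ccl3 (-1.40 ± 0.20) fell. The list did not pass then (adjusted p = 0.977; median 0.09 and mean 0.46 but the test pointing down). MHC class II presentation passed at day 14 alone, with 8 of 9 genes higher (8 adjusted over the list alone; adjusted p = 1.82e-08). H2-Ab1 rose from 413 to 2070 CPM (2.32 ± 0.30). At day 7 the list had adjusted p = 0.58. Chemokines rose at day 7, 4 of 8 (5, with 1 lower, adjusted over the list alone; adjusted p = 0.00111), with Cxcl16 at 2.94 ± 0.28, but had adjusted p = 0.0939 at day 14. The p53 response rose at day 7, 2 of 12 (2 adjusted over the list alone; adjusted p = 0.00906; adjusted p = 0.336 with an estimated correlation), with the cyclin gene Ccng1 at 1.00 ± 0.27, and had adjusted p = 0.759 at day 14. Lipid handling (7 lower and 1 higher of 14; 9 and 2 adjusted over the list alone; adjusted p = 0.0016; adjusted p = 0.0789 with an estimated correlation) and dissociation and immediate early genes (6 lower, 1 higher of 14; 8 and 2 adjusted over the list alone; adjusted p = 0.00354; adjusted p = 0.203 with an estimated correlation) fell at day 14. The fatty acid receptor gene Cd36 changed by -2.44 ± 0.26 and the transcription factor gene Egr1 by -2.75 ± 0.30. Proliferation (adjusted p = 0.528 and 0.412), alternative activation (0.58 and 0.764; medians -0.02 and -0.20, means 1.19 and 1.57, test pointing up) and nintedanib target kinases (0.727 and 0.977; medians 0.08 and 0.13, means -0.11 and -0.18, test pointing down) did not pass. Of the kinases 3 of 13 were measured, and Csf1r rose (0.69 ± 0.20 and 1.43 ± 0.18) and Flt1 fell (-1.12 ± 0.18 and -2.10 ± 0.17).

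In interstitial macrophage-like cells the largest increases after bleomycin included Spp1, Gpnmb and Arg1. Spp1 rose from 14.8 to 12317 CPM at day 7 (9.80 ± 0.57, adjusted p = 3.9e-12) and from 38.4 ± 7.70 to 24662 ± 9980 CPM at day 14 (9.30 ± 0.50, adjusted p = 3.4e-13). Gpnmb, a glycoprotein gene of lipid-laden macrophages, had 2 UMIs in day 7 controls (ratio 157, 43.6 to 1300.4) and rose from 15.6 to 1017 CPM at day 14 (5.92 ± 0.42). Arg1 was not detected in controls and was at least 22.7-fold and at least 33.5-fold higher (261 ± 104 and 276 ± 19.1 CPM). The coagulation factor gene F7 was higher at least 17.1-fold and at least 26.6-fold. At day 7 the adhesion gene Cd24a (at least 18.4-fold), the collagen-cleaving cathepsin gene Ctsk (at least 8.37-fold), the protease inhibitor gene Spint1 (at least 7.84-fold), the metalloproteinase gene Mmp19 (at least 7.66-fold) were higher with no control count. So were the amino acid transporter gene Slc36a2 (at least 7.59-fold), the inhibitory receptor gene Cd200r1 (at least 7.16-fold), the vesicle acidification gene Dmxl2 (at least 6.67-fold) and the receptor gene Gpr171 (at least 5.68-fold). At day 14 Slc36a2 (at least 9.57-fold), the DNA repair gene Zranb3 (at least 7.14-fold) and Timp1, an inhibitor of matrix degradation (at least 5.09-fold), were higher. Other increases were those of Ccl17 (ratio 56.5, 10.1 to 2230.9), the fatty acid-binding protein gene Fabp4 (52.5, 9.42 to 2076.2) and the proton pump gene Atp6v0d2 (48.1, 16.5 to 233.5).

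Among the largest decreases, Plac8, a monocyte and granulocyte gene, fell from 3300 to 92.3 CPM at day 7 (-5.19 ± 0.44) and from 3905 to 76.5 CPM at day 14 (-5.69 ± 0.45). Ly6c2, the classical monocyte antigen, fell from 1904 to 35.3 CPM at day 14 (-5.78 ± 0.41). The interferon-inducible membrane gene Ifitm6 (-6.08 ± 0.42 and -5.58 ± 0.40), the neutrophil antigen gene Cd177 (-4.04 ± 0.76 and -5.43 ± 0.62) and the interferon gene Ifit1bl1 (-4.05 ± 0.77 and -4.22 ± 0.60) fell on both days. Ms4a4c (-4.59 ± 0.39) and Ifi205 (-4.36 ± 0.43), both monocyte genes under interferon control, fell at day 14. At day 7 the eosinophil attractant gene Ccl24 (-5.64 ± 1.07) and the hyaluronan receptor gene Lyve1 (-4.05 ± 1.06, adjusted p = 0.0115), both of resident interstitial macrophages, were lower. In all 1089 of 10140 genes passed at day 7 (733 higher, 356 lower), 656 without day 7 control pool 3. At day 14, 1038 passed (668 higher, 370 lower). The days shared 366 higher (48.3 for independent lists) and 221 lower genes (13.0). No overlap was seen in 38.9% and 35.9% of tested genes, against 10% by chance, and, as the naming rule requires, in each gene named here. The share that was higher depended on scaling. It was 67.3% and 64.4% with TMM, 46.8% and 49.9% with RLE scaling, where the median of all genes shifted by -0.25 and -0.15, and 32.8% and 38.7% with DESeq2. Control values came from 20 to 37 cells per pool. Cluster 13, marked by Ccl8 and Pf4, held 50.0% and 46.3% of the class in controls, and cluster 25, marked by Rsad2 and Cxcl10, 33.3% and 38.9%. After bleomycin cluster 10, marked by Mmp12 and Clec4n, held 43.4% and 28.3%, and cluster 7, marked by Gpnmb and Trem2, 26.0% and 51.6%. The values therefore compare different states of the class.

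Fibrosis-associated genes rose in this class too, 11 of 13 at day 7 and all 13 at day 14 (12 and 13 adjusted over the list alone; medians 2.45 and 2.43; adjusted p = 1.12e-14 and 7.91e-17), with Fabp5, a fatty acid-binding protein gene, at 6.52 ± 0.53 and 4.61 ± 0.39. All 15 interferon response genes fell on both days (15 adjusted over the list alone; medians -2.41 and -3.18; adjusted p = 1.04e-10 and 7.91e-17). With an estimated correlation day 7 had adjusted p = 0.159. Isg15 fell by -2.46 ± 0.33 and -3.18 ± 0.33 and Usp18, its deconjugase, by -2.93 ± 0.35 and -4.01 ± 0.31. With each cell classed by its own marker score, the day 7 list pointed up (adjusted p = 0.294). Isg15 at day 7 (2.57) and Usp18 at days 7 and 14 (0.33 and 8.50) were then higher without passing. Cluster 25 (Rsad2, Cxcl10) held 33.3% and 38.9% of the class in controls and 7.26% and 4.40% after bleomycin. The fall of the interferon list may therefore reflect class make-up, since no change within clusters was computed for it under bleomycin. Dissociation and immediate early genes fell, 11 and 10 of 14 (11 and 11 adjusted over the list alone; adjusted p = 3.07e-07 and 7.18e-07), with Atf3 at -2.22 ± 0.24 and -1.63 ± 0.25 and Jun at -1.82 ± 0.24 and -1.66 ± 0.23. Genes for uptake of dead cells and lysosome rose, 8 and 9 of 12 (8 and 9 adjusted over the list alone; adjusted p = 1.21e-06 and 2.48e-08), with the lysosomal protease genes Ctsd (4.76 ± 0.35 and 3.58 ± 0.31) and Ctsl (2.92 ± 0.32 and 3.37 ± 0.28). Glycolysis and hypoxia genes rose, 6 of 12 on both days (8 and 7 adjusted over the list alone; adjusted p = 0.000262 and 0.000138), Ldha by 2.08 ± 0.24 and 1.39 ± 0.21. Lipid handling rose, 8 and 7 of 14 (8 and 8 adjusted over the list alone; adjusted p = 0.012 and 1.07e-06; at day 7 adjusted p = 0.211 with an estimated correlation), with the lipoprotein lipase gene Lpl at 1.42 ± 0.30 and 3.53 ± 0.29. Its medians of 1.42 and 1.84 become 1.08 and 1.44 when genes without control counts stand at their bound.

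Resident alveolar macrophage identity genes rose, 4 of 10 on both days (5 and 4 adjusted over the list alone; adjusted p = 0.0468 and 0.000589; adjusted p = 0.361 and 0.0731 with an estimated correlation). Their medians of 3.71 and 3.07 become 0.91 and 0.40 at the bound. Bhlhe41, a transcriptional repressor gene on this list, had 1 and 2 UMIs in controls (ratio 12.9, 2.30 to 508.6, at day 7 and 11.9, 3.28 to 98.3, at day 14). MHC class II presentation fell at day 7, 4 of 11 with 1 higher (6 and 1 adjusted over the list alone; adjusted p = 0.0422; adjusted p = 0.481 with an estimated correlation), H2-Eb1 by -1.08 ± 0.26 while Ctss, which cleaves the invariant chain, rose by 1.87 ± 0.26. At day 14 it had adjusted p = 0.21 (median -0.49, mean 0.18, test pointing down). Cholesterol synthesis (2 of 16, 5 adjusted over the list alone; adjusted p = 0.0157; adjusted p = 0.32 with an estimated correlation) and growth factors (2 of 11, 2 adjusted over the list alone; adjusted p = 0.0336; adjusted p = 0.24 with an estimated correlation) rose at day 14. The mevalonate pathway gene Mvd rose by 2.21 ± 0.46 and Igf1 by 1.53 ± 0.33. At day 7 these lists had adjusted p = 0.224 and 0.12. Their day 14 medians of 0.98 and 0.83 become 0.62 and 0.67 at the bound. Complement (0.224 and 0.397), chemokines (0.232 and 0.353), p53 response (0.237 and 0.559), interstitial macrophage identity (0.428 and 0.559), alternative activation (0.696 and 0.353), proinflammatory (0.428 and 0.559; at day 14 median -0.08, mean 0.77, test pointing up), proliferation (0.601 and 0.353; medians 0.47 and 0.41, 0.29 and 0.02 at the bound, test pointing down) and target kinases (0.12 and 0.47; medians -0.89 and -0.27, means 0.46 and 1.21, test pointing down) did not pass by adjusted p. Within them Pf4, a platelet-type chemokine gene of interstitial macrophages, fell by -1.83 ± 0.32 and -2.23 ± 0.31.

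At day 14 Arg1 and Sdc4 were higher with nintedanib in both macrophage classes by the edgeR fit over all groups, but the calls in interstitial macrophage-like cells did not hold under many alternatives. Arg1 rose from 117 ± 17.8 to 344 ± 128 CPM in alveolar macrophage-like cells (1.58 ± 0.26, adjusted p = 0.00438) and from 276 ± 19.1 to 719 ± 312 CPM in interstitial macrophage-like cells (1.38 ± 0.27, adjusted p = 0.0441). Sdc4, a heparan sulfate proteoglycan gene of the cell surface, also rose in both (1.66 ± 0.28, adjusted p = 0.00718; 0.99 ± 0.19, adjusted p = 0.0441). The matrix glycoprotein gene Ecm1 (1.51 ± 0.20, adjusted p = 0.000875), the glucocorticoid-induced chaperone gene Fkbp5 (1.36 ± 0.20, adjusted p = 0.00222), the cold-inducible RNA-binding gene Cirbp (1.18 ± 0.23, adjusted p = 0.0197) rose in alveolar macrophage-like cells. So did the clathrin adaptor gene Ap1s2 (1.07 ± 0.16, adjusted p = 0.00229), the tubulin gene Tuba1c (0.64 ± 0.13, adjusted p = 0.0406) and Ms4a8a, a membrane gene of tissue-repair macrophages (0.62 ± 0.13, adjusted p = 0.0425). Chil3, a chitinase-like protein gene induced by type 2 cytokines, rose in interstitial macrophage-like cells from 420 ± 92.2 to 1678 ± 764 CPM (2.00 ± 0.37, adjusted p = 0.0299). The transglutaminase subunit gene F13a1 rose there from 45.0 ± 4.70 to 120 ± 62.9 CPM (1.44 ± 0.29, adjusted p = 0.0441). Chil3 is also on the marker list of alveolar macrophages, and F13a1 on that of classical monocytes. Whether cells of those types within the class carry these rises was not tested directly. The 3 nintedanib pools lay above the 3 bleomycin pools in each gene named so far in this paragraph, which the naming rule requires. Arg1 and Sdc4 did not pass in interstitial macrophage-like cells with cells of at least 500 genes (adjusted p = 0.0744 and 0.0632), marker-score classes (0.225 and 0.196), free RNA subtracted (0.0639 and 0.0582), RLE scaling (0.0559 and 0.0559), the 2 groups alone in the fit (0.211 and 0.211) or any of 4 of the 6 pools left out, nor Arg1 with thinned libraries (0.91). Their changes stayed positive. Chil3 and F13a1 did not pass there with cells of at least 500 genes, marker-score classes, DESeq2, thinned libraries or the same 4 pools left out, nor F13a1 with RLE scaling, free RNA subtracted or the 2 groups alone. With the replicate block, edgeR called each of these genes there (adjusted p = 0.00167 for Arg1, 0.000103 for Sdc4, 0.000209 for Chil3 and 0.00039 for F13a1). Chil3 in alveolar macrophage-like cells passed with the block (adjusted p = 6.01e-05) but not in the main edgeR fit (0.0654). In alveolar macrophage-like cells Arg1 did not pass with the 2 groups alone (0.0547) or without bleomycin pool 3 (0.083). Nor did Sdc4 with DESeq2 (0.0633), marker-score classes (0.766), the 2 groups alone (0.133) or without pool 3 of either group (0.162 and 0.137). Chosen after the values were seen, the ribonuclease gene Ear6 (2.07 ± 0.37) rose, and the heparanase gene Hpse (-1.46 ± 0.28) and the class I genes H2-Q7 (-1.68 ± 0.32) and H2-Q6 (-1.97 ± 0.40) fell in alveolar macrophage-like cells. The metallothionein gene Mt2 (1.60 ± 0.29) rose and the dendritic cell marker Cd209a (-3.20 ± 0.52) fell in interstitial macrophage-like cells.

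These genes were few. In alveolar macrophage-like cells 14 passed at day 14 (11 higher, 3 lower; 510 with unadjusted p under 0.05; 8 with DESeq2), 79 with a replicate block. The count was 7 and 4 without bleomycin pools 2 and 3, and 6, 47 and 5 without nintedanib pools 1, 2 and 3. In interstitial macrophage-like cells 6 passed (5 higher, 1 lower; 583 unadjusted; 11 with DESeq2), 103 with the block. The count was 29 and 3 without bleomycin pools 1 and 3, and 1, 60 and 0 without nintedanib pools 1, 2 and 3. Genes and directions depended on the setting in this class. DESeq2 had 6 higher and 5 lower, with 4 of the 6 edgeR genes among them, and a fit of the 2 groups alone had 1 higher and 5 lower, with 2 of the 6. Without bleomycin pool 1 there were 11 higher and 18 lower, and without bleomycin pool 2 there were 4, all lower. With cells of at least 500 genes 1 passed, which was lower, and with RLE scaling or free RNA subtracted 3. With marker-score classes or thinned libraries edgeR called 0 (701 and 51 unadjusted). No overlap was seen in 10.1% and 10.4% of tested genes. This has no chance value here, since both contrasts met the criterion for pairing by replicate number. At day 7, edgeR called 0 genes in alveolar macrophage-like cells (270 with unadjusted p under 0.05; 0 with DESeq2) and 1 in interstitial macrophage-like cells (205 unadjusted; 1 with DESeq2; 3 with the block). It was S100a9, a calprotectin subunit gene of neutrophils, which fell from 16.97 ± 10.17 to 2.55 ± 0.55 CPM (-2.58 ± 0.28, adjusted p = 0.0354) without overlap of pools. At under 20 CPM it was named after its value was seen. Without bleomycin pools 1 and 2 the count was 2 and 5, and without bleomycin pool 3 or any nintedanib pool edgeR called 0. For the mean of both days edgeR called 0 genes in either class (397 and 478 unadjusted; 1 and 1 with DESeq2), 19 and 39 with the block, and 8 and 20 without day 14 nintedanib pool 2. For the difference of the nintedanib effect between days edgeR called 0 and 0 genes (349 and 308 unadjusted; 0 and 2 with DESeq2), and 0 and 19 with the block. The day 7 mice had nintedanib from day 0 to 6 and the day 14 mice from day 7 to 13. Day and dosing window therefore cannot be told apart, and the mean of days joins both windows.

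**Figure D3:**
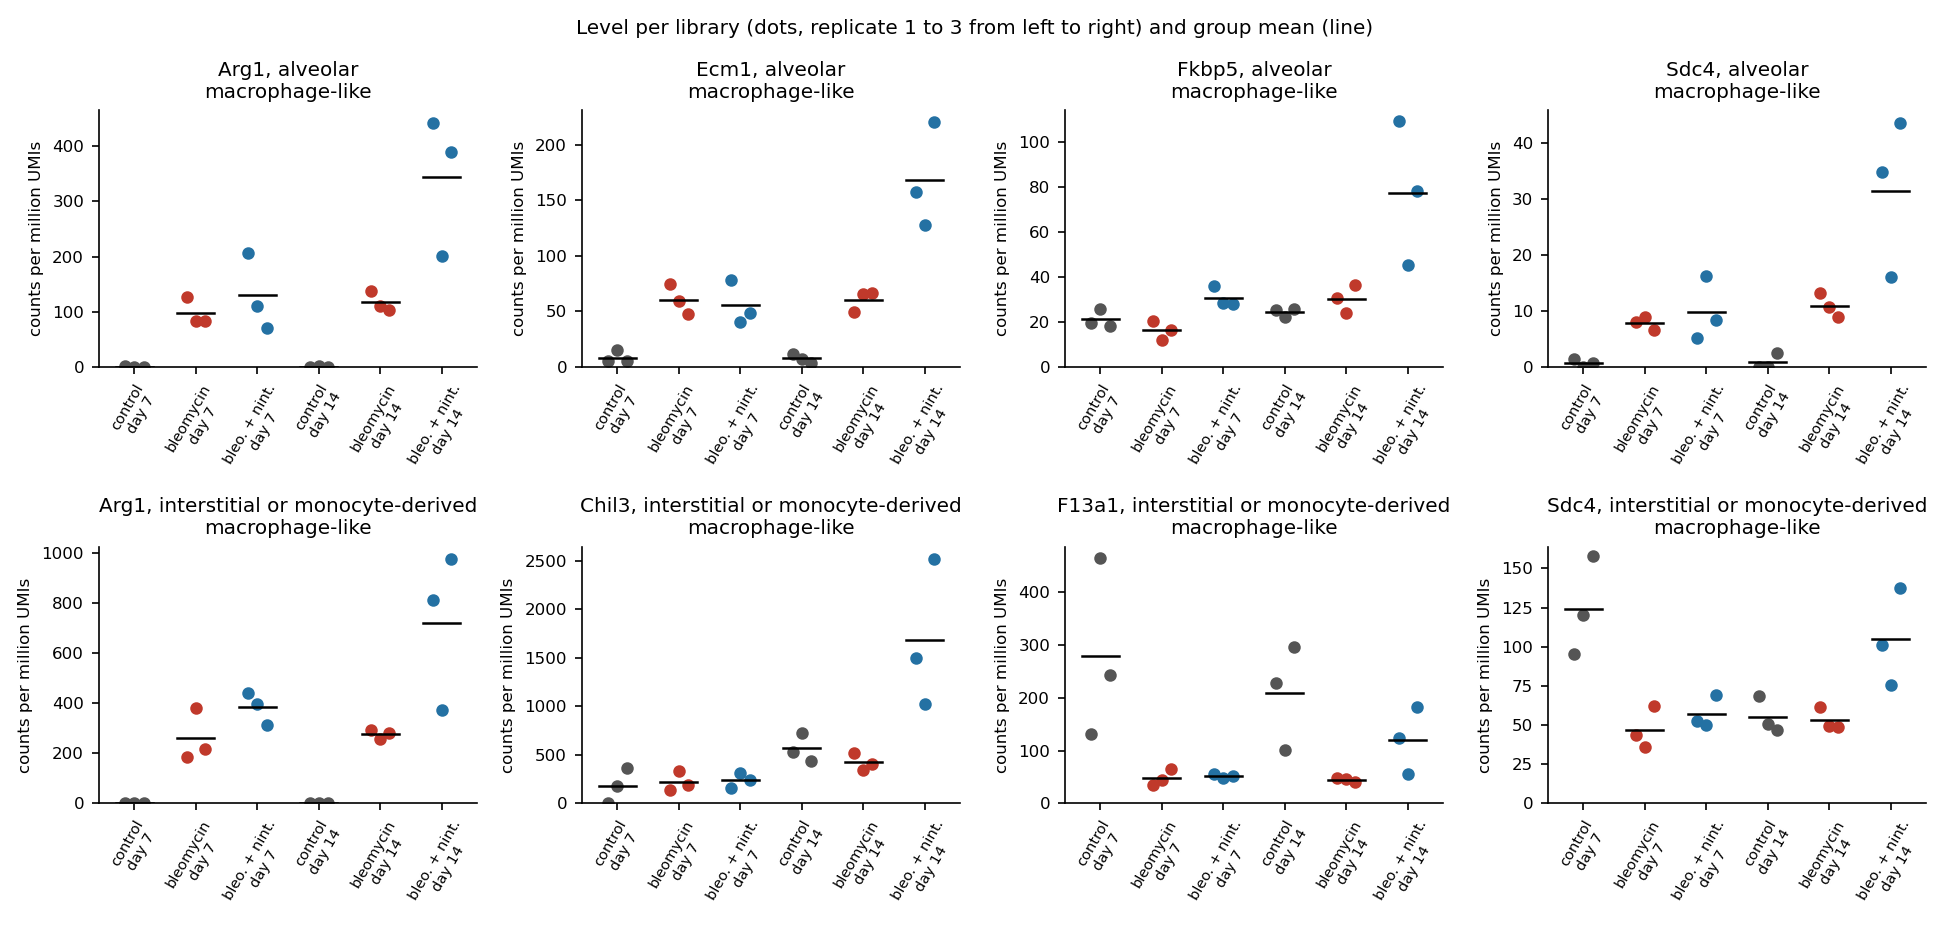
Some of the genes that passed between nintedanib and bleomycin at day 14, by pool, in all 6 groups.

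The number of gene lists passing under nintedanib was matched or exceeded in other splits of the libraries. At day 14 other splits gave up to 9 and 12 lists in alveolar and interstitial macrophage-like cells, against 7 and 5. Those that part all 3 same-numbered pairs gave up to 4 and 6. For the mean of days drawn splits gave up to 9 and 11, against 6 and 7. Among gene groups, alternative activation rose under nintedanib over both days in both classes, and in interstitial macrophage-like cells at day 14. For alveolar macrophage-like cells the mean of days had adjusted p = 0.000708 (median 0.11; 0 of 8 over all genes, 3 adjusted over the list alone), with Arg1 (0.96 ± 0.20), Chil3 (0.67 ± 0.17) and the mannose receptor gene Mrc1 (0.35 ± 0.10). Day 14 had adjusted p = 0.0112 (1 of 8 over all genes; 3 higher and 1 lower adjusted over the list alone; adjusted p = 0.106 with an estimated correlation) and day 7 did not pass (0.0701). The day 14 median was 0.07, with 5 members higher and 3 lower in value. In interstitial macrophage-like cells day 14 had adjusted p = 8.5e-06 (median 0.33; 2 of 14 over all genes, 6 adjusted over the list alone), with the haemoglobin scavenger gene Cd163 (2.43 ± 0.59) and Mrc1 (0.69 ± 0.18) beside Chil3 and Arg1. The mean of days had adjusted p = 3.38e-06, and day 7 adjusted p = 0.0234 (adjusted p = 0.169 with an estimated correlation). Cluster 13 (Ccl8, Pf4) held 15.6% of this class with bleomycin and 22.3% with nintedanib at day 14. Averaged within clusters, Chil3 changed by 2.13 and Arg1 by 1.26, while Cd163 and Mrc1 were not looked at singly. Cholesterol synthesis moved the other way. All 16 genes were lower at day 14 in both classes, with medians of -0.45 and -0.34. Of the 16, 0 passed in alveolar macrophage-like cells over all genes and 9 adjusted over the list alone (adjusted p = 9.15e-14; adjusted p = 0.0803 with an estimated correlation), with Fdft1 at -0.66 ± 0.19 and Sqle at -0.60 ± 0.20. The other class had 0 passing over all genes and 2 adjusted over the list alone (adjusted p = 1.06e-09, and 0.031 with an estimated correlation), Cyp51 at -0.63 ± 0.15 and Sqle at -0.73 ± 0.19. For the mean of days the list had adjusted p = 6.63e-07 (adjusted p = 0.181 with an estimated correlation) and 2.14e-09.

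Interferon response and MHC class II genes were lower as lists with nintedanib, without a gene passing over all genes. In interstitial macrophage-like cells all 15 interferon genes were lower at day 7 (median -0.41; 0 adjusted over the list alone; adjusted p = 8.22e-13, and 0.169 with an estimated correlation). At day 14, 13 were lower (median -0.57; 5 adjusted over the list alone; adjusted p = 1.06e-09, and 0.194 with an estimated correlation), with Oasl2 at -1.03 ± 0.26. Cluster 25 (Rsad2, Cxcl10) held 7.26% of this class with bleomycin and 4.84% with nintedanib at day 7, and 4.40% and 2.48% at day 14. As mean log CPM, the median change was -0.67 and -0.53 in the class, and -0.60 and -0.47 averaged within clusters. For alveolar macrophage-like cells the list had adjusted p = 0.0339 and 0.000108 (adjusted p = 0.72 and 0.168 with an estimated correlation), 0 and 2 genes adjusted over the list alone, Ifi27l2a at -0.94 ± 0.23 on day 14. The class II genes were lower at day 14 in all 9 and all 11 measured members (medians -0.50 and -0.34; 0 adjusted over the list alone; adjusted p = 2.24e-06 and 8.14e-08; adjusted p = 0.145 and 0.144 with an estimated correlation). They were lower at day 7 in interstitial macrophage-like cells (adjusted p = 0.00743, and 0.463 with an estimated correlation). Proinflammatory genes were lower at day 7 in 13 of 15 members in alveolar macrophage-like cells (median -0.45; 0 over all genes, 4 adjusted over the list alone; adjusted p = 5.46e-06, and 0.193 with an estimated correlation). Il1b changed by -0.72 ± 0.17 and Cxcl1 by -1.42 ± 0.40. They were lower in all 15 in interstitial macrophage-like cells (median -0.25; 0 adjusted over the list alone; adjusted p = 6.04e-06; adjusted p = 0.137 with an estimated correlation). At day 14 they did not pass (0.383 and 0.506).

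Interstitial macrophage identity genes were higher at day 14 in both classes (medians 0.35 and 0.15; 0 over all genes, 1 and 5 adjusted over the list alone; adjusted p = 0.0112 and 8.5e-06; adjusted p = 0.168 and 0.194 with an estimated correlation), with the transcription factor gene Maf at 0.65 ± 0.21 in interstitial macrophage-like cells. There cluster 13 (Ccl8, Pf4) held 15.6% of the class with bleomycin and 22.3% with nintedanib. The median of 0.15 became 0.09 when averaged within clusters. Fibrosis-associated genes were lower at day 14 in alveolar macrophage-like cells (median -0.16; 0 over all genes; adjusted over the list alone Mmp14 and Fabp5 lower and Emp1 higher; adjusted p = 0.00551, and 0.168 with an estimated correlation), Mmp14 at -0.77 ± 0.21 and Fabp5 at -0.84 ± 0.24. In interstitial macrophage-like cells they had adjusted p = 0.136, and 0.0205 with the block. Dissociation and immediate early genes at day 7 (adjusted p = 0.0257, and 0.72 with an estimated correlation) and p53 response at day 14 (adjusted p = 0.0456, and 0.594 with an estimated correlation) were lower in alveolar macrophage-like cells, and cholesterol synthesis at day 7 in interstitial macrophage-like cells (adjusted p = 0.0214, and 0.463 with an estimated correlation). No other list passed on a single day. With each pool left out, the day 14 calls of cholesterol synthesis and class II in both classes, of alternative activation, interferon response and interstitial identity in interstitial macrophage-like cells, and the day 7 proinflammatory calls in both classes held. For alveolar macrophage-like cells alternative activation at day 14 did not pass without pool 1 of either group. Nor did interferon response without bleomycin pool 1, fibrosis-associated genes without bleomycin pool 2 or nintedanib pool 1, and interstitial identity without bleomycin pool 3 or nintedanib pool 1. With the block, lists passing in addition at day 14 were immediate early genes (0.0122, higher) and resident identity (0.0494, lower) in alveolar macrophage-like cells. In the other class they were lysosome (0.043, higher), glycolysis (0.043, higher) and p53 response (0.0123, lower), and complement (0.0151) and immediate early genes (0.0203) were lower there at day 7. The target kinases, of which 3 and 5 of 13 were measured, had adjusted p = 0.416 and 0.363 in alveolar and 0.676 and 0.845 in interstitial macrophage-like cells.

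**Figure D4:**
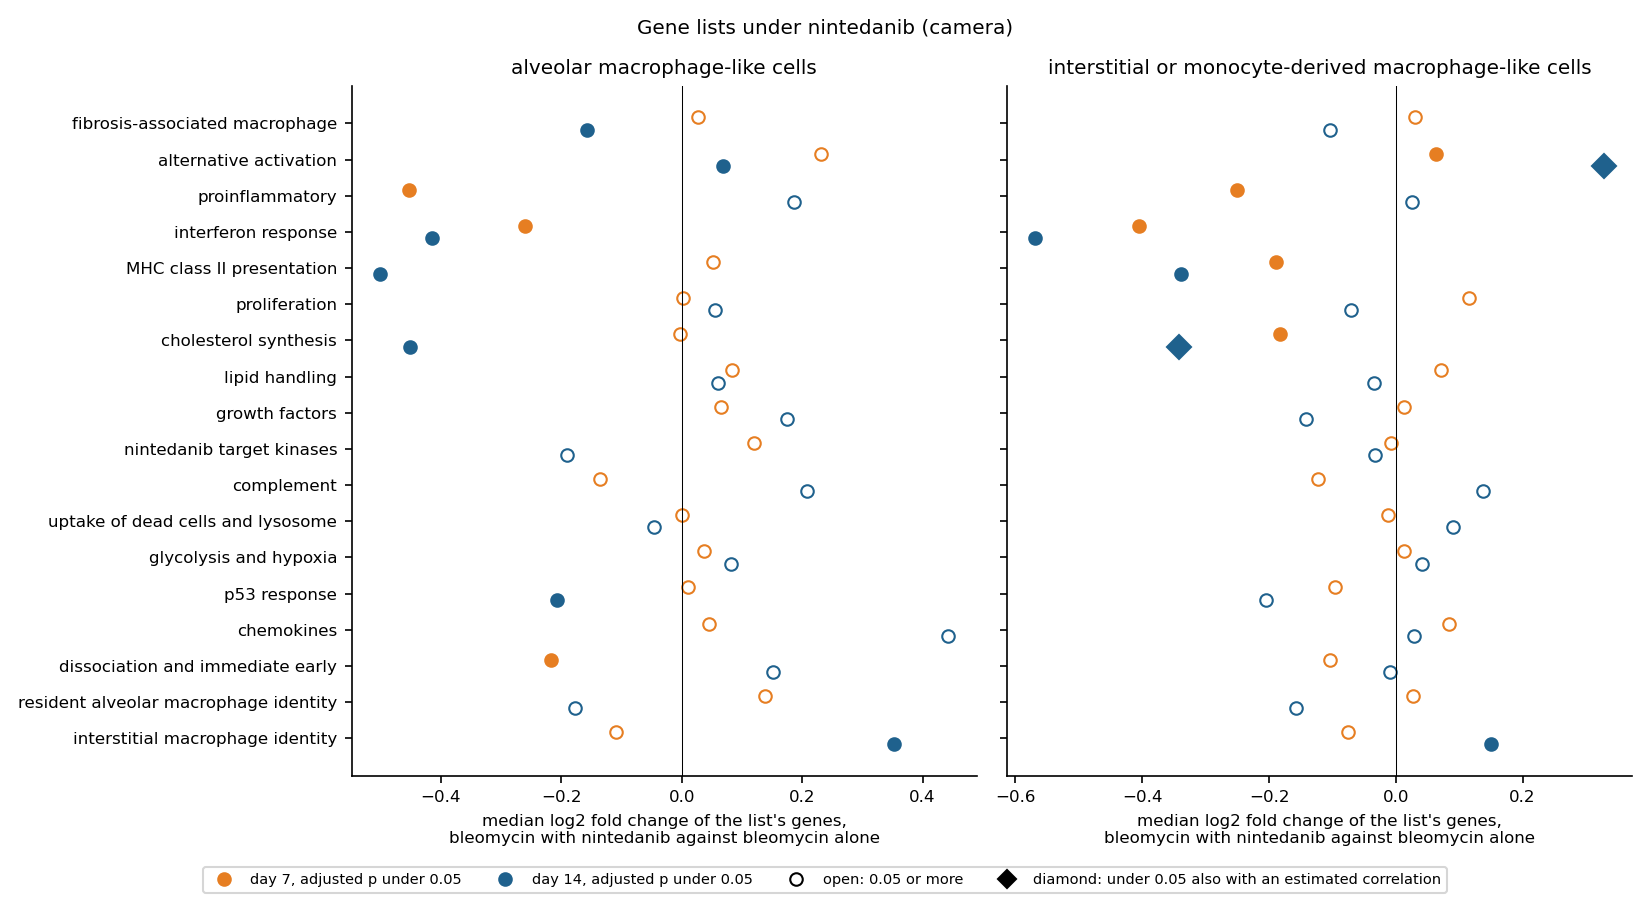
Gene lists between nintedanib and bleomycin, as the median log2 change of the members of each list in both macrophage classes.

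Genes that bleomycin had lowered in interstitial macrophage-like cells were lower still with nintedanib as a set, but not under each alternative. The 200 genes lowered at the other day had a median of -0.16 at day 7 (adjusted p = 6.47e-10; adjusted p = 0.055 with an estimated correlation; 64 of 200 in the opposite direction) and -0.25 at day 14 (adjusted p = 1.15e-11; 47 of 200). They did not pass with marker-score classes (adjusted p = 0.0505 and 0.955) or with libraries thinned to the smallest (0.113 and 0.196), and 5 and 8 of 10 splits of the libraries gave as many passing sets. Cluster 25 (Rsad2, Cxcl10) held 33.3% and 38.9% of this class in controls, 7.26% and 4.40% with bleomycin, and 4.84% and 2.48% with nintedanib. Its part in the fall of the lowered set was not tested. The 200 genes raised by bleomycin had medians of 0.03 and -0.03 in this class. In alveolar macrophage-like cells neither set passed, with medians of -0.04 (adjusted p = 0.674) and 0.07 (0.0956) for raised and lowered genes at day 7, and -0.06 (0.0722) and -0.05 (0.133) at day 14.

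Bleomycin also changed lung cells other than macrophages. Endothelial-like cells had 398 genes at day 7 (258 higher, 140 lower) and 539 at day 14 (330 higher, 209 lower). Increases were led by Lrg1, which alters TGF-beta signalling in vessels (165 to 2835 CPM, 4.08 ± 0.26; then 3.69 ± 0.25), and the venular chemokine receptor gene Ackr1 (6.48 ± 1.33 and 4.78 ± 1.01). Cyp1a1, a target of the aryl hydrocarbon receptor (-3.37 and -5.37), and the lung methyltransferase gene Inmt (-1.54 and -2.33) fell. T cell-like cells had 71 genes (65 higher, 6 lower) and 109 (90 higher, 19 lower). Higher genes included the costimulatory genes Tnfrsf9 (3.28 ± 0.34 and 3.38 ± 0.30) and Tnfrsf4 (2.64 ± 0.30 and 3.68 ± 0.32), Foxp3 (3.04 ± 0.49) and the repair growth factor gene Areg (3.01 ± 0.46). Ccl5 (-1.18 ± 0.23) and the cytotoxic T cell gene Cd8a (-0.76) were lower. Conventional dendritic cell-like cells had 323 genes (157 higher, 166 lower) and 215 (126 higher, 89 lower), with the lectin genes Clec4n (4.41 ± 0.48) and Asgr2 (4.25 and 4.62) higher and the transferrin gene Trf (-1.99 ± 0.19) lower. Fibroblast-like cells had 397 genes at day 7 (191 higher, 206 lower), with the haptoglobin gene Hp from 19.2 to 980 CPM (5.59 ± 0.41) and Igfbp3 lower (-3.66 ± 0.69). Epithelial-like cells had 139 at day 14 (67 higher, 72 lower), with Cldn4 (6.10 ± 0.90) and Clu (3.77 ± 0.67), both of injured alveolar epithelium, higher and the type 2 cell genes Lamp3 (-3.87 ± 0.78) and Etv5 (-4.24) lower. Between nintedanib and bleomycin, edgeR called 0 genes in 26 of 28 comparisons in classes other than the 2 macrophage classes (54 to 603 with unadjusted p under 0.05; 0 to 7 with DESeq2). At day 14 it called 2 in classical monocyte-like cells, among them the inhibitory lectin gene Cd33 (1.66 ± 0.30, adjusted p = 0.0445), and 1 in epithelial-like cells, the secretory cell gene Scgb3a1 (4.14 ± 7.17 to 11687 ± 9598 CPM, adjusted p = 0.00102). Epithelial-like pools held only 20 to 46 cells in that comparison and 20 to 54 for bleomycin at day 14. Which epithelial cells were caught may thus enter these values, which was not tested.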

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

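Tests in this part were planned before the results were seen.

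In alveolar macrophage-like cells the effect of bleomycin differed between day 7 and day 14 for 23 of 8479 genes, by a test of the difference itself (edgeR, adjusted p = 0.000658 to 0.0419; 529 genes with unadjusted p under 0.05; 27 with DESeq2). Differences are given as the day 14 effect minus the day 7 effect on the log2 scale. Of the class II pathway, 5 genes passed at day 14 and not at day 7, with differences of 2.53 for H2-Eb1, 2.34 for H2-Ab1 (-0.01 at day 7, 2.32 at day 14), 2.17 for H2-Aa, 2.01 for Cd74 and 1.47 for H2-DMb1. In the other 18 genes the difference was negative. The chemokine gene Ccl3 rose by 0.81 at day 7 and fell by 1.40 at day 14 (difference -2.22), and the cytokine gene Tnf (-2.16), the oxysterol gene Ch25h (-2.31), the niacin receptor gene Hcar2 (-1.59), the immediate early gene Egr1 (-2.15) and Phlda1 (-1.61) also differed. Further genes with a lower effect at day 14 were the scavenger receptor gene Marco (-2.92; 0.83 at day 7, not passing, and -2.09 at day 14), Krt79 (-2.72), Ear1 (-1.52), the neuropeptide gene Gal (-2.05), the cyclin gene Ccnd2 (-2.30), the lipase gene Lipf (-2.93), the transcription regulator Wwtr1 (-2.14), the lectin gene Clec1b (-1.20), Rpl3l (-1.58), Fam89a (-1.78) and the gene model Gm42772 (-2.23). Cluster 8, marked by Marco and Ear1, held 59.1% of the class with bleomycin at day 7 and 13.0% at day 14, so the days differ in the make-up of the class. With the 12 libraries left out singly the count was 1 to 32. It was 1 without day 7 control pool 1 or day 7 bleomycin pool 2, 5 without day 7 control pool 3 and 15 without day 14 bleomycin pool 1. The count therefore depends on single pools, although leaving a pool out also lowers power. With a replicate block it was 78.

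In interstitial macrophage-like cells 2 genes differed between days (edgeR; 677 with unadjusted p under 0.05; 11 with DESeq2). The fatty acid receptor gene Cd36 had a difference of 2.59 ± 0.41 (-0.59 at day 7, 2.01 at day 14, adjusted p = 0.00878), and the monocyte gene Ly6c2 a difference of -2.81 ± 0.51 (-2.97 and -5.78, adjusted p = 0.0345). With the 12 libraries left out singly the count was 0 to 7. It was 0 by edgeR without day 14 control pool 1 (650 with unadjusted p under 0.05), 1 without day 14 control pool 2, day 7 bleomycin pool 2 or day 14 bleomycin pool 3, 4 without day 14 bleomycin pool 1 and 7 without day 7 control pool 3. With a replicate block it was 9.

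Of 30 drawn splits of the libraries, 2 gave as many genes as these day differences in alveolar macrophage-like cells (23; highest of the others 517) and 2 in interstitial macrophage-like cells (2; highest of the others 141), so these splits do not exclude chance. In both classes the 1 other split keeps day 14 whole and exchanges 2 of 3 libraries between bleomycin and control at day 7. Its counts of 517 and 141 point to a structure of the samples, the bleomycin response itself, which enters the difference in that split. The other 28 gave 0 genes in alveolar macrophage-like cells and 0 to 1 in interstitial macrophage-like cells (edgeR). Single outlying pools were not tested within the groups of 3.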

How the results depend on the processing

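Of 25 pairs of a result and an alternative, 2 were chosen after seeing the data: clustering without the genes called, and leaving out together the 6 libraries with replicate number 2, which had the fewest UMIs. Tests with both are named below. Of 510 counts and tests of comparisons under an alternative or with a library left out, 351 (68.8%) stayed within 1.5 times or on the same side of the threshold, and of 16773 values for named genes, lists and classes 15729 (93.8%) did. A stricter mitochondrial limit and a denominator without non-immune cells moved none of the comparison counts. Unless stated, the cause was not tested. Where edgeR called 0 genes under an alternative or without a library, 21 to 701 had an unadjusted p under 0.05, and DESeq2 counts are given below. Below, values are for alveolar macrophage-like (AM) and interstitial macrophage-like (IM) cells. Depth limits the IM controls most, with 48765 to 136591 UMIs per pool.

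Without an expression filter, nintedanib called 9 AM genes at day 7, 81 at day 14 and 35 over both days, with 86 and 21 for the bleomycin and nintedanib day differences, and 20, 118, 85, 29 and 38 in IM. With the replicate block the AM counts were 79 at day 14, 19 over both days and 78 for the bleomycin day difference, and in IM 3 at day 7, 103, 39, 9 and 19 for the nintedanib day difference. With the block 0 shares passed in each of the 4 share comparisons, since 6 sign flips allow no p below 0.0312. DESeq2 gave 8 AM genes at day 14 and 1 over both days, and in IM 11, 1, and 11 and 2 for the day differences. RLE scaling gave 0 and 3 IM genes under nintedanib at days 7 and 14, cells with at least 500 genes 0 and 1, and doublets kept 15 at day 14. With only the groups of a contrast in the fit, there were 2 AM genes at day 14, 40 for the AM bleomycin day difference, 0 IM genes at day 7 and 10 for the IM bleomycin day difference.

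With classes from marker scores, bleomycin called 880 AM genes at day 7, and 195 and 237 IM genes at days 7 and 14 with a median shift of all genes of 0.47 and 0.45. Nintedanib called 5 AM genes at day 14, 0 and 0 IM genes and 0 classes and 0 clusters, and the IM bleomycin day difference 0. With free RNA subtracted and the expression filter applied anew there were 9 AM genes at day 14, 0 and 3 IM genes and 1 for the IM bleomycin day difference. Thinned to the smallest library, bleomycin called 678 and 955 AM genes and 259 and 236 IM genes, nintedanib 2 AM genes at day 14 and 1 over both days, 0 and 0 IM genes, and the IM bleomycin day difference 0. Fewer counts lower these by construction. Without the libraries numbered 2, nintedanib called 43 AM genes at day 14 and 6 over both days, and in IM 0 at day 7, 61 at day 14 and 14 over both days, with 0 and 10 for the bleomycin and nintedanib day differences. For nintedanib, edgeR on cell counts called 2 classes and 0 clusters, finer clustering 0 clusters, and clustering without called genes 0, against 9 for bleomycin.

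Sets of bleomycin genes under nintedanib changed as follows. The AM raised set at day 14 passed (lower) with at least 500 genes (adjusted p = 0.0399), marker scores (0.000655) and free RNA subtracted (0.0266), the AM lowered set at day 14 (lower) and the IM raised set at day 7 (higher) with at most 50 genes (0.00305 and 0.0274), and both AM sets at day 7, each opposite to bleomycin, without the libraries numbered 2 (0.0423 and 0.0423). The IM lowered sets lost their call with marker scores (0.0505 and 0.955) and thinning (0.113 and 0.196), and at day 7 with an estimated correlation (0.055).

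With single libraries left out, ranges for AM were 801 to 1324 and 1476 to 1896 (bleomycin), 0 to 0, 4 to 47 and 0 to 8 (nintedanib day 7, day 14 and both), and 1 to 32 and 0 to 2 (day differences). For IM they were 656 to 1029 and 697 to 1039, 0 to 5, 0 to 60 and 0 to 20, and 0 to 7 and 0 to 9. The fewest came without day 7 control pool 1 (801 and 1) and control pool 3 (656), the most under nintedanib without day 14 nintedanib pool 2 (47, 60, 8, 20, 2 and 9). Adjusted p for the AM raised and lowered sets ranged from 0.000438 to 0.979 and 0.00303 to 0.218 at day 7, and 0.000538 to 0.577 and 0.00393 to 0.389 at day 14, and for IM from 0.0102 to 0.983 and 4.75e-11 to 0.00031, and 0.0261 to 0.956 and 6.08e-14 to 0.00101. Class shares passing ranged from 3 to 6 and 0 to 2, cluster shares from 5 to 5 and 0 to 1.

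Directions reversed in 16 cases. The AM p53 response list nintedanib day 14 pointed up under thinning (adjusted p = 0.757) and without nintedanib pool 1 (0.562; range with each pool left out 4.52e-05 to 0.633), the AM raised set at day 7 without bleomycin pool 1 (0.000438), and the IM class II list under bleomycin at day 7 without a filter (0.301). With marker scores the IM interferon list at day 7 pointed up (0.294), and log2 changes without passing were 6.57 for I830127L07Rik, 5.73 for Ifit1bl1, 5.90 for Cd177, 0.33 for Usp18, 0.57 for Ifit3, 2.57 for Isg15 and 1.51 for Oasl2 at day 7, and 3.02 for I830127L07Rik, 8.50 for Usp18, 0.000252 for Ifit1 and 0.0508 for Hmgb2 at day 14.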

Other observations

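Among tests in this part, the 2 with free RNA subtracted from the day 14 nintedanib genes were chosen after the result was seen. The others were planned.

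Genes called under nintedanib at day 14 (14 in alveolar macrophage-like cells, 6 in interstitial macrophage-like cells) could stand for a shift of cells among clusters of a class or for free RNA from other cells. The tables argue against free RNA, and against a shift among the clusters found here, as the whole cause. Within clusters the log2 changes were a median of 0.925 and 0.835 times those of the whole class (lower quartiles 0.892 and 0.7495), although the dendritic cell marker Cd209a kept 0.443. Cluster 5 held 87.0% of alveolar macrophage-like cells with bleomycin and 88.8% with nintedanib. Shares this close leave little room for a shift between clusters, but they also put the ratio near 1 almost by construction. Shifts among finer states were not tested, and the called genes were not left out of the clustering. With free RNA subtracted the ratios were 1.01 and 1.00, with median sizes of 1.48 before and 1.51 after (standard errors 0.265 and 0.280) and of 1.52 before and after (0.289 and 0.303), while over the genes tested without subtraction edgeR still called 9 of the 14 and 0 of the 6 (highest adjusted p 0.122 and 0.0801), and with the expression filter applied anew 9 and 3, as errors were larger at changes of about equal size. Pairing by replicate number stays open, with 79 and 103 genes under a block, and a biological effect of nintedanib remains a hypothesis.

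RNA of C1q genes and Spp1, abundant in interstitial macrophage-like cells after bleomycin, rose in alveolar macrophage-like and also in T cell-like cells (Spp1 3.48 ± 0.33 and 4.55 ± 0.35, Apoe 2.64 and 3.96). If free RNA reaches all cells of a library alike, B cell-like cells give its level. Alveolar macrophage-like cells held at least 82.2 times the UMIs of these genes per B cell-like cell in the 6 bleomycin libraries. Most were Spp1 (25.2 of 28.1 per cell at day 7). In day 7 controls Spp1 was already 1.17, against 0.00907 in B cell-like cells, so the ratio was high before bleomycin. C1qb rose from 0.00654 to 1.61 UMIs per cell at day 7, beside 0.0471 in B cell-like cells. Spp1 rose from 1.17 to 25.2, beside 0.142. These levels argue against free RNA as the source there, but not against interstitial macrophage-like cells or doublets within the class. T cell-like cells held at most 1.47 times the B cell level, so free RNA may account for these genes in them, and the T cell counts of called genes include them. Endothelial-like and NK cell-like cells held 0.325 and 0.272 UMIs of these genes per cell with bleomycin at day 7, beside 0.257 in B cell-like cells. Free RNA may thus enter their counts of called genes too, which was not tested.

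S100a9, lower under nintedanib at day 7 in interstitial macrophage-like cells (-2.58 ± 0.28), was also lower in B cell-like (-2.05 ± 0.53), T cell-like (-1.28 ± 0.55), NK cell-like (-1.11 ± 0.74) and endothelial-like cells (-1.49 ± 0.36), but not in alveolar macrophage-like cells (0.01 ± 0.43). The median of the 5 classes was -1.27, less than the change in interstitial macrophage-like cells, which argues against free RNA as the whole cause, although the B cell value lies within its error. UMIs per cell fell from 0.117 to 0.0172 in interstitial macrophage-like cells and from 0.0246 to 0.00545 in B cell-like cells. S100a8 changed by 0.05 ± 0.17 in the former and -2.40 ± 0.47 in the latter. With bleomycin it stood at 108 CPM in interstitial macrophage-like cells, against 16.97 for S100a9, so a loss of like size would hardly move it. Its lack of change therefore cannot decide on neutrophil RNA. Neutrophil-like cells were 4.97 ± 3.80% of cells with bleomycin and 1.06 ± 0.612% with nintedanib at day 7 (exact p = 0.2 at day 7 and 0.27 over both days). A part from free neutrophil RNA may therefore remain. Neutrophils caught with macrophages as doublets may also add to it, which was not tested. An effect on the macrophages is a hypothesis.

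Every arrangement of 3 libraries against 3 was fitted, and 10 splits are too few for a share under 0.05, so each contrast is given only with its real value and, after it, the highest of the other 9. For alveolar macrophage-like cells under bleomycin, 1 of 10 splits gave as many genes at day 7 (1370; highest other 1) and 1 at day 14 (2049; 0), and 1 gave as many lists on each day (12; 11 and 12; 10). For interstitial macrophage-like cells 1 split each gave as many genes (1089; 0 and 1038; 11), and 5 and 4 as many lists (8; 13 and 9; 12). Endothelial-like cells had 1 split each (398; 0 and 539; 25), as did T cell-like (71; 0 and 109; 16) and conventional dendritic cell-like cells (323; 0 and 215; 8).

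Under nintedanib at day 7, 10 of 10 splits gave as many genes in alveolar macrophage-like cells (0; highest other 1), 6 as many lists (3; 6) and 10 as many response sets (0; 2), and in interstitial macrophage-like cells 4, 8 and 5 did (1 gene; 5, 5 lists; 9, 1 set; 2). At day 14 these were 1, 4 and 10 (14 genes; 7, 7 lists; 9, 0 sets; 2) and 2, 7 and 8 (6 genes; 10, 5 lists; 12, 1 set; 2), and 1 in classical monocyte-like cells (2 genes; 1). Where replicate numbers pair the libraries, the 3 other splits that part all 3 pairs gave at most 0 genes in both classes at day 14 and 0 in interstitial macrophage-like cells at day 7 (edgeR), and 4, 6 and 8 lists (1, 2 and 2 response sets), whereas splits parting 1 pair gave up to 7, 10 and 5 genes. For bleomycin at day 14 in alveolar macrophage-like cells they gave at most 0 genes (edgeR) and 10 lists. Of 30 drawn splits for the mean of days, 30 gave as many genes in both classes (0; 5 and 0; 2), and 9 and 16 as many lists (6; 9 and 7; 11). For the nintedanib day difference 30 and 30 did (0; 58 and 0; 71). The 58 and 71 genes come from 1 split, which parts 2 of 6 pairs and points to a structure of the samples. The 11 other drawn splits that part 2 of 6 pairs gave at most 3 and 4 genes, so the number of pairs parted does not account for it. They were not matched on which replicate numbers were put together on each day, so replicate number stays open.

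Proliferating macrophage-like cells were 1.99 ± 2.45% of cells with bleomycin at day 7 and 1.5002 ± 2.07% at day 14, and 76.9% of them, counted before doublets were left out, came from libraries with replicate number 1. Between libraries of a group, chi-square per degree of freedom was 12.1 to 48.0, so no 2 libraries of the same group were copies of each other. In the day 14 nintedanib libraries Arg1, Chil3 and F13a1 were lowest in pool 2 in the classes where they are shown. Of 10 unnamed clusters, 7 had 44.2% to 87.8% of their cells scored as doublets, and the other 3 had 5.79% to 6.18%.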
